A study of Arabidopsis thaliana with 4 samples.

How the data were processed

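RNA from rosette leaves of 3-week-old Arabidopsis thaliana plants (Col-0 background) was measured on 4 Affymetrix ATH1 arrays, per the labels. The arrays form 4 groups of 1 array each: plants carrying the empty pCP60 vector and plants of line 52 overexpressing ERD15, each sprayed either with a mock solution holding 0.07% ethanol or with 100 µM abscisic acid (ABA) in the same concentration of ethanol, and collected after 90 min. Rosettes of 3 plants were pooled per sample, per the labels of 3 of the 4 samples, while those of the vector mock sample do not state it. Groups were taken from the sample titles and source names. One characteristic of the overexpressor samples uses the words for a gene knock-out, which their titles and source names contradict, and the overexpressor reading was used throughout.

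The deposited values are signal intensities on a linear scale, made with MAS5, per the submitters' processing notes, with no version given in the sources used here. MAS5 subtracts a local background and the mismatch probes, summarises a probe set to 1 value and scales each array to a common mean. The deposited trimmed means, with 2% of the non-control probe sets removed at each end, lay between 99.1 and 99.3 on the 4 arrays, so that a change of total RNA is not visible in these values. No detection call was used here, so that a low signal cannot be told from background gene by gene.

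The table holds 22810 probe sets, of which 64 are controls. The platform annotation used here pairs 13513 probe sets with 1 gene, 503 with several genes and 8730 non-control probe sets with none; 13436 of the single-gene probe sets matched a gene of the TAIR10.1 RefSeq table, which was used for names and gene order only. ERD15 itself has no paired probe set in that annotation, so its level is not analysed here and the genotype labels were not checked against it. Of the 277 genes in the 21 gene lists fixed before the data were examined, 28 were measured, here meaning paired with a probe set of their own that passed the filter.

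From the deposited intensities, each array was scaled to a 2%-trimmed mean of 100 over non-control probe sets, values under the pooled 25th percentile (a signal of 13.3) were raised to it, and log2 was taken. Probe sets with a mean signal under the pooled 40th percentile (29.0) were left out, and the probe set with the highest mean stood for a gene, which left 7322 genes; 73 of them had more than 1 probe set. A fold that involves the floor is a lower limit and is written "at least". The comparisons over both genotypes or both treatments used limma 3.58.1 in R 4.3.3 with an additive model of genotype and treatment over the 4 arrays, eBayes with a trend on signal, and Benjamini-Hochberg adjustment at 0.05. This model has 1 residual degree of freedom per gene, and its residual comes from the difference of the ABA effect between the genotypes. An interaction can thus enter only as error. The eBayes prior had a median of 2925 degrees of freedom, which means that a gene's SE was set by its signal and hardly by its own residual. A large interaction therefore hardly raised the SE, and a gene low on 1 array alone could pass for both effects. AT5G55450, low on vector mock, did so with an SE of 0.278 and a difference of the ABA effect of -4.21. The ABA effect within 1 genotype, the genotype effect within 1 treatment and their difference compare single arrays: they have no replicate check, and are given as values and as counts at 2-fold, with no test.

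On simulated ABA effects over 7322 genes, with 200 genes changed and equal spread between genes, the limma step recovered 33.4% of genes changed by a log2 of 1, 74.4% at 1.5, 87.6% at 2 and 98.4% at 3, and 5.71% of its calls were false. With a spread that varied between genes it recovered 20.4%, 53.4%, 77.6% and 95.2%, and 13.6% of its calls were false. The simulated noise was independent between genes, took its spread from the fit itself and held no interaction. Errors that genes share on an array were not simulated, so the false shares may not carry over to these data. A list with 3 or more measured genes was described by the percentile of its median log2 difference among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. In a check on 100 random lists of 4 genes, 5 unchanged lists lay outside the central 95% for the ABA effect, and 100 were found after a log2 of 1 was added. Such percentiles describe these arrays and are not p-values.

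The rule for named genes was fixed before the data were examined: the 12 highest and 8 lowest genes past the limma threshold for ABA that were also at least 2-fold changed in the same direction in both genotypes; the 10 highest and 10 lowest genes for genotype, at least 2-fold in the same direction under both treatments; and the 5 largest and 5 smallest differences of the ABA effect among the 7157 genes above the floor on every array. ERD15 and all clade A phosphatases and PYR/PYL receptors were to be named too, but no probe set is paired with them in the annotation used, and the unnamed probe sets were not searched for them. In each list, the members with the largest differences were named. Alternatives fixed beforehand were quantile normalization, the values as deposited, arrays centred on the median, no floor, a floor at the 40th percentile, the 25th percentile added in place of a floor, no filter, a filter at the 60th percentile, the mean over probe sets, eBayes without a trend or with a robust prior, and thresholds of 1.5-fold and 4-fold. After seeing the data, all probe sets whether named or not, the arrays left out in turn for the vector mock and overexpressor mock samples, counts of genes separated by each split of the 4 arrays, and families of genes by symbol were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The number of arrays limits the precision throughout.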

Results

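Transcript levels in rosette leaves were measured on 4 ATH1 arrays, 1 for each combination of genotype (empty vector or ERD15 overexpressor) and spray (mock or 100 µM ABA for 90 min). ABA is the plant hormone of drought and osmotic stress, and ERD15 is a small protein named for its early induction by dehydration. The design addresses which genes respond to ABA, which differ between the genotypes, and whether ERD15 overexpression alters the ABA response. The level of ERD15 was not analysed here, since no probe set is paired with it, and the genotype labels are therefore taken as given. All arrays had a similar median signal, between 39.95 and 45.8. The correlation of log2 signals across genes ran from 0.878 between vector mock and overexpressor ABA to 0.935 between both ABA arrays. Pairs that held vector mock were the lowest, at 0.878, 0.893 and 0.902, against 0.911 to 0.935 for the others. Vector mock also had the most genes at the floor, 72 against 33 to 35. The ratio of 3' to 5' signal of the actin control lay between 5.33 and 6.52, that of GAPDH between 1.54 and 2.00 and that of ubiquitin between 1.64 and 2.18. The arrays were not alike in all controls: the 25S ribosomal RNA control read 1833 on vector mock, 2109 on vector ABA, 262 on overexpressor mock and 832.5 on overexpressor ABA, and the highest signal was 6232 on overexpressor mock against 9280 to 11160 on the others. The hybridization spike-ins bioB, bioC, bioD and cre were lower than on vector mock by log2 differences of -0.86, -1.23, -1.31 and -0.97 on overexpressor mock, of -0.73, -0.54, -0.63 and -0.44 on vector ABA, and of -0.09, -0.20, -0.50 and -0.19 on overexpressor ABA.

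The first comparison asks which genes respond to ABA whatever the genotype. Among the 7322 genes, which leave out probe sets with no gene name, the largest rises were those of ZW9, which encodes a TRAF-like protein (log2 3.35 ± 0.29 SE, 10.2-fold), PUB19, a U-box E3 ubiquitin ligase (3.22 ± 0.30, 9.29-fold), EXPA16, an expansin (2.88 ± 0.32, 7.36-fold), and XTH18, a xyloglucan endotransglucosylase/hydrolase (2.84 ± 0.27, 7.17-fold). Their limma adjusted p-values were 7.55e-28, 1.99e-22, 8.87e-16 and 2.92e-22. AT1G73480, an alpha/beta hydrolase, rose 7.06-fold, with a log2 difference of 2.82 in each genotype. AT1G52000, a jacalin-like lectin, was at the floor on both mock arrays and rose at least 6.23-fold. AT3G02480, a late embryogenesis abundant protein, rose at least 4.71-fold, and AT4G36010, a thaumatin-like protein, at least 4.67-fold. AT5G03230 and AT2G28400, which share a domain of unknown function, rose 5.16-fold and 4.70-fold, AT4G17470 rose 4.73-fold and CPUORF47, a gene with a conserved upstream open reading frame, at least 4.54-fold. The limma p-values for ABA and for genotype rest on an SE shared by genes of like signal. With 1 array per group they do not measure variation between plants. That of ZW9 was 1.83e-05 by limma with quantile normalization.

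The largest fall under ABA was that of AT4G21870, an HSP20-like chaperone, with a log2 change of -5.01 ± 0.28 (32.2-fold, limma adjusted p = 8.21e-66); its log2 difference was -4.98 in vector plants and -5.04 in the overexpressor. AT5G62360, a pectin methylesterase inhibitor-like protein, fell 18.6-fold (log2 -4.22 ± 0.30), and TBL45, of the family that acetylates wall polysaccharides, fell 7.21-fold (-2.85 ± 0.27). The ethylene response factor genes AT5G61590 and AT5G07580 fell 6.28-fold and 5.48-fold. AT3G52950 fell 5.09-fold, the MATE transporter AT3G23550 4.67-fold and AT2G04795 4.52-fold.

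**Figure D1:**
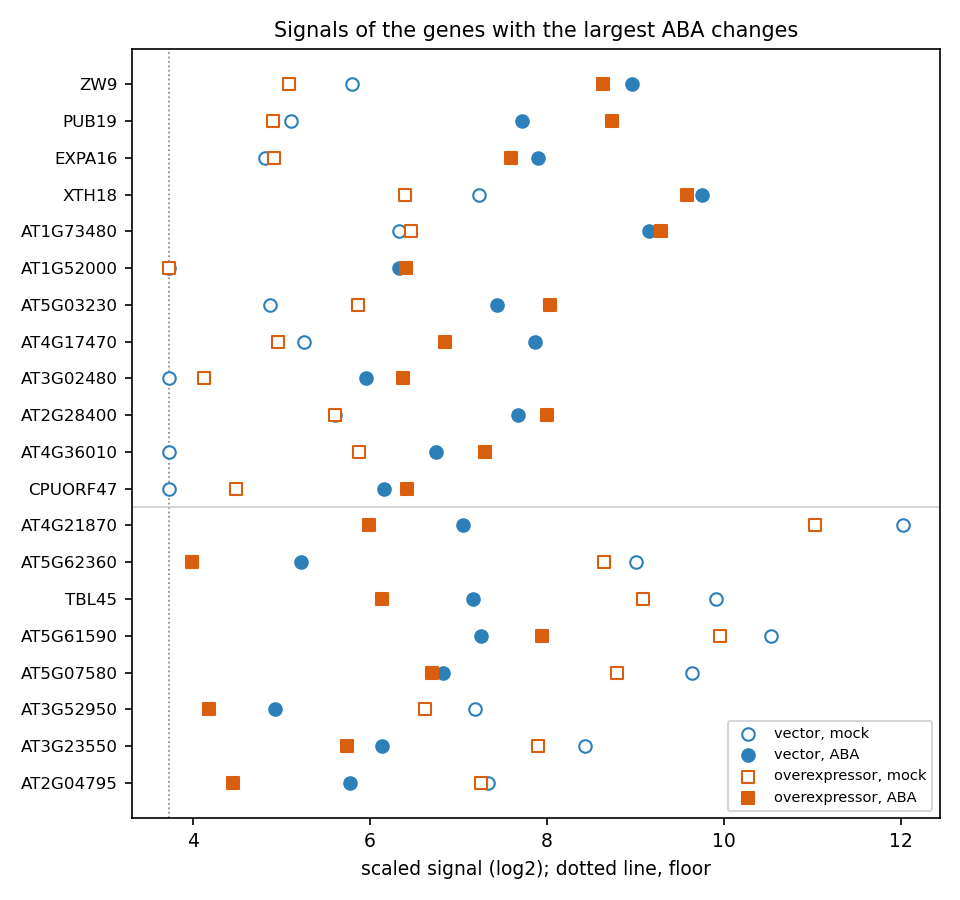
Scaled log2 signal (horizontal axis) of the 20 genes named by rule for the ABA effect, with 1 symbol for each of the 4 arrays: open for mock, filled for ABA, circles for vector and squares for the ERD15 overexpressor. The 12 upper genes are higher on both ABA arrays and the 8 lower genes lower on both, as for AT4G21870, which went from 12.02 to 7.05 in vector plants and from 11.03 to 5.99 in the overexpressor; coinciding symbols overlap, and the dotted line marks the floor.

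In total, 228 of 7322 genes passed the limma threshold for ABA over both genotypes, 122 higher and 106 lower, and 113 of them were at least 2-fold changed in the same direction in each genotype. Both ABA differences had the same sign for 221 of the 228 genes and opposite signs for 7. Without a test, 71 genes were at least 2-fold higher in both genotypes, against 17.8 for independent lists of the same sizes, and 76 were at least 2-fold lower in both, against 13.9. The split of the 4 arrays by treatment separated 99 genes by at least 2-fold, with both ABA arrays on the same side of both mock arrays, whereas the crossed split, which follows neither treatment nor genotype, separated 13. The limma count depends on the normalization and on how the spread is modelled: it was 115 with quantile normalization, all among the 228, and 9 without a trend in eBayes. With no filter on dim genes it was 0 of 13356 genes by limma. Of these, 641 had an unadjusted p under 0.05, no more than chance alone would give.

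Among the lists fixed beforehand, the ABA and dehydration response genes stood highest for ABA. Of the 4 measured members, 3 rose over all genes tested and 3 when adjusted over the list alone, and the list's median log2 change of 1.28 lay at percentile 100.0 of the random lists. COR15A, which protects chloroplast membranes during dehydration and cold, rose by a log2 of 2.01 ± 0.28 (limma adjusted p = 1.59e-10). The dehydrin genes LTI30 and COR47 rose by 1.42 ± 0.29 and 1.14 ± 0.31 (adjusted p = 8.37e-05 and 0.0127), and COR15B had a difference of 0.52 ± 0.30 (adjusted p = 0.701). The rise of COR47 was 0.50 in vector plants and 1.78 in the overexpressor. Its log2 signal was 9.18 on overexpressor mock, against 10.41 to 10.95 on the other arrays. No member passed for genotype on either count; the list's median genotype difference was -0.10, at percentile 35.2, and its ABA effect was larger in the overexpressor by a median of 0.50, at percentile 94.6.

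Of the 3 measured auxin response genes, WES1, which conjugates auxin to amino acids, rose by 1.88 ± 0.34 (adjusted p = 5.10e-06) and was the 1 member past the threshold over all genes and adjusted over the list alone. GH3.3 and IAA29 had ABA differences of 0.24 ± 0.31 and -0.03 ± 0.48. The list's medians were 0.24 for ABA (percentile 85.1), -0.30 for genotype (7.82) and 0.10 for the difference of the ABA effect (41.9), and no member passed for genotype. Of the 4 reference genes PEX4, GAPC2, AT2G28390 and AT4G34270, none passed for either effect on either count. Their medians were 0.12 for ABA (percentile 80.8), -0.12 for genotype (24.8) and -0.14 for the difference of the ABA effect (28.2).

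The 3 measured photosynthesis genes encode rubisco activase (RCA), a light-harvesting protein (LHCB4.2) and protochlorophyllide oxidoreductase (PORB), and none passed for ABA or genotype on either count. For the difference of the ABA effect their list had a median of 1.16, at percentile 99.98, and this median was 0.45 with quantile normalization. RCA was at a log2 signal of 13.14 on vector mock, 12.75 on vector ABA, 12.00 on overexpressor mock and 12.78 on overexpressor ABA, and LHCB4.2 was likewise lowest on overexpressor mock, at 11.93 against 12.50 to 12.90. PORB was lowest on vector ABA, at 9.96 against 11.03 to 11.40. The brightest genes were lower on the overexpressor mock array as a class: of 38 genes with a signal of 3000 or more, 37 were lower there than on vector mock, with a median of -0.75, which became -0.03 with quantile normalization. The list's medians were 0.12 for ABA (percentile 72.8) and -0.51 for genotype (8.21).

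10 lists had 1 or 2 measured genes, and 7 had none: the clade A type 2C phosphatases, the PYR/PYL receptors, the ABA-activated kinases and ABF factors, ABA synthesis and catabolism, and markers of vasculature, of roots, and of flowers and seeds. Of the rapid stress response genes, WRKY53 rose with ABA by 1.15 ± 0.29 (adjusted p = 0.00400), while the zinc finger gene STZ, with 0.79 ± 0.32 (adjusted p = 0.246), passed when adjusted over the list alone, as did WRKY53. WRKY53 also passed for genotype when adjusted over the list alone (0.75 ± 0.29). Both measured salicylic acid genes, GRX480 and SAG101, had genotype differences of 0.88 ± 0.42 and 0.84 ± 0.34 that passed when adjusted over the list alone and not over all genes. That of SAG101 lay under mock (1.62, against 0.06 under ABA), where vector mock was its lowest array, and that of GRX480 was 1.13 under mock and 0.64 under ABA. Of the cell wall loosening genes, XTH16 was lower in the overexpressor (-0.93 ± 0.27, adjusted p = 0.0402), on both counts, and EXPA8 had an ABA difference of -0.84 ± 0.34 that passed over the list alone. The clock gene GI had a genotype difference of 0.81 ± 0.29 that passed over the list alone, and that was 0.16 under mock and 1.46 under ABA. Over all genes its limma adjusted p was 0.172. A list with 1 measured gene, as here, applies no adjustment, and a list with 2 hardly any. By limma, 641 of 7322 genes had an unadjusted genotype p under 0.05. Neither effect passed on either count for the jasmonate and ethylene gene PDF1.2, the heat shock gene AT5G37670, the glucosinolate gene BCAT4, the flavonoid genes DFR and UF3GT, the senescence gene WRKY6 or the guard cell gene FMA. Their ABA differences were -0.05, -0.22, -0.02, -0.13, -0.45, at least 1.34 and 0.19, and their genotype differences 0.84, 0.45, 0.37, -0.54, 0.45, at least 0.29 and -0.50, in the same order. The -0.05 of PDF1.2 is the mean of opposite differences, -1.36 in vector plants and 1.26 in the overexpressor.

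In vector plants, 355 genes were at least 2-fold higher and 390 at least 2-fold lower on the ABA array than on the mock array, and in the overexpressor 367 were higher and 260 lower. Quantile normalization turned both splits, to 407 higher and 301 lower in vector plants and to 219 higher and 316 lower in the overexpressor. Across genes, which are not independent replicates, the ABA differences in both genotypes correlated with a Pearson r of 0.153, and with 0.317 among the 4669 genes above the 60th percentile of signal. Among the 166 genes with a mean log2 difference of 1 or more, the median was 1.61 in vector plants and 1.21 in the overexpressor, and 100 of the 166 had the larger rise in vector plants (60.2%, 95% Wilson interval 52.6 to 67.4, which covers the sampling of genes only). Of the 122 genes past the limma threshold that were higher with ABA, 78 had their lowest signal on vector mock. Genes chosen as higher with ABA are mostly lowest on a mock array by selection. This count therefore largely restates the larger rise in vector plants, seen in 79 of the 122. Among the 148 genes at -1 or less, the medians were -1.48 and -1.33, and 86 had the larger fall in vector plants (58.1%, 50.1 to 65.8). With quantile normalization the medians of the lower genes were -1.40 and -1.40, with 78 of 150 larger in vector plants (52.0%), and with no filter 52.8% of the higher genes had the larger rise in vector plants.

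**Figure D2:**
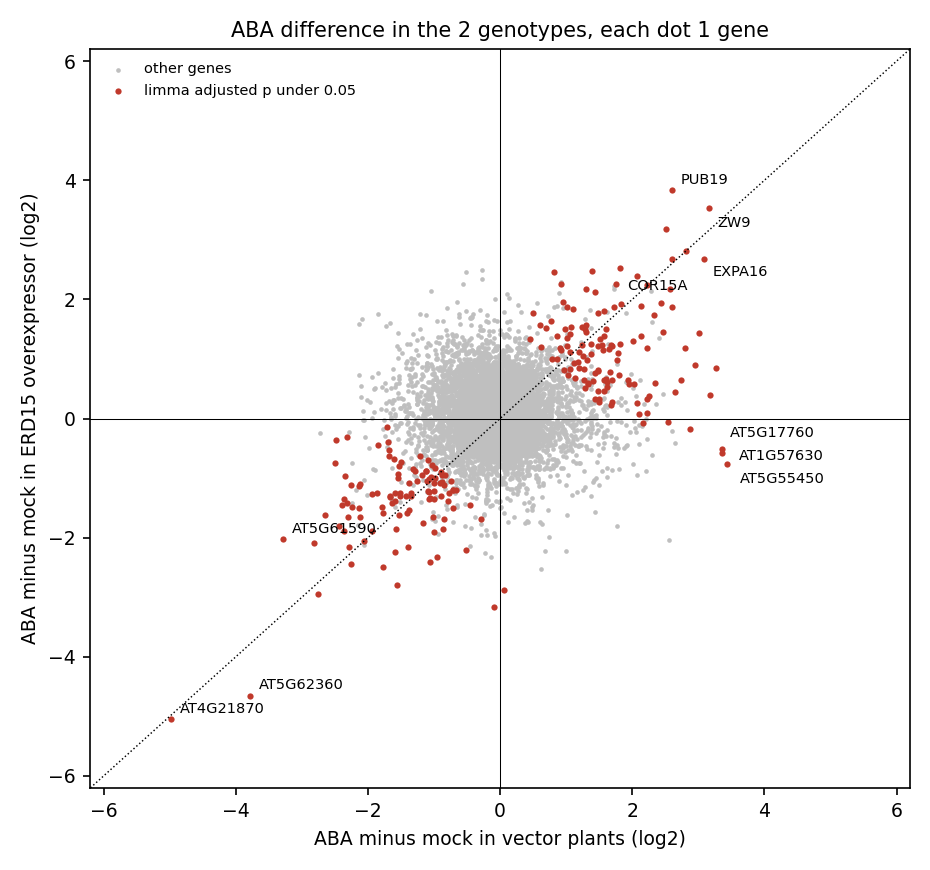
ABA minus mock log2 difference of each of 7322 genes in vector plants (horizontal axis) and in the ERD15 overexpressor (vertical axis), with the 228 genes past the limma threshold in red and a dotted line of equal difference. AT4G21870 lies near the line at -4.98 and -5.04, while AT5G55450 and AT1G57630 lie to the right below 0, with 3.44 and 3.36 in vector plants and -0.77 and -0.58 in the overexpressor.

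Between the genotypes, the gene that stood out under both treatments was AT5G19540, which was at the floor on both vector arrays and at log2 signals of 8.65 and 8.64 on the overexpressor arrays, at least 30.2-fold higher (limma adjusted p = 3.84e-43). AT2G44240 was at least 19.0-fold higher (log2 4.25 ± 0.38), with at least 5.72 under mock and 2.78 under ABA. The AAA-type ATPase genes AT5G17760 and AT3G28510 were at least 8.91-fold and at least 4.49-fold higher, and AT3G27930 at least 3.56-fold. These folds average unlike differences, and each of these genes was at the floor on vector mock only. In the same order they were at least 34.03-fold, at least 9.82-fold and at least 6.195-fold under mock. Under ABA they were 2.33-fold, 2.05-fold and 2.04-fold. AT5G41400 was 3.53-fold higher, the lipid transfer-like gene AT4G12490 3.19-fold, AT5G19875 2.99-fold, AT2G25730 2.96-fold and AT5G43310 2.82-fold. AT5G41400 was 6.05-fold higher under mock and 2.06-fold under ABA, while AT4G12490 and AT5G43310 had the larger difference under ABA. THI2.2, which encodes a thionin, an antimicrobial peptide, was at the floor on both overexpressor arrays and at 6.26 and 6.54 on the vector arrays, at least 6.36-fold lower (adjusted p = 0.00219). AT1G11850 was at least 4.57-fold lower, the glycine-rich protein genes AT1G04800 and AT4G29020 4.54-fold and 3.72-fold, and AT5G48490, a lipid transfer protein gene related to DIR1, 3.98-fold (log2 -1.99 ± 0.31, adjusted p = 9.36e-08). AT1G13650 was 3.48-fold lower, AT5G13140 3.03-fold, the GDSL lipase gene AT2G04570 2.98-fold the aspartyl protease gene AT3G54400 2.87-fold and AT5G63180 2.65-fold.

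**Figure D3:**
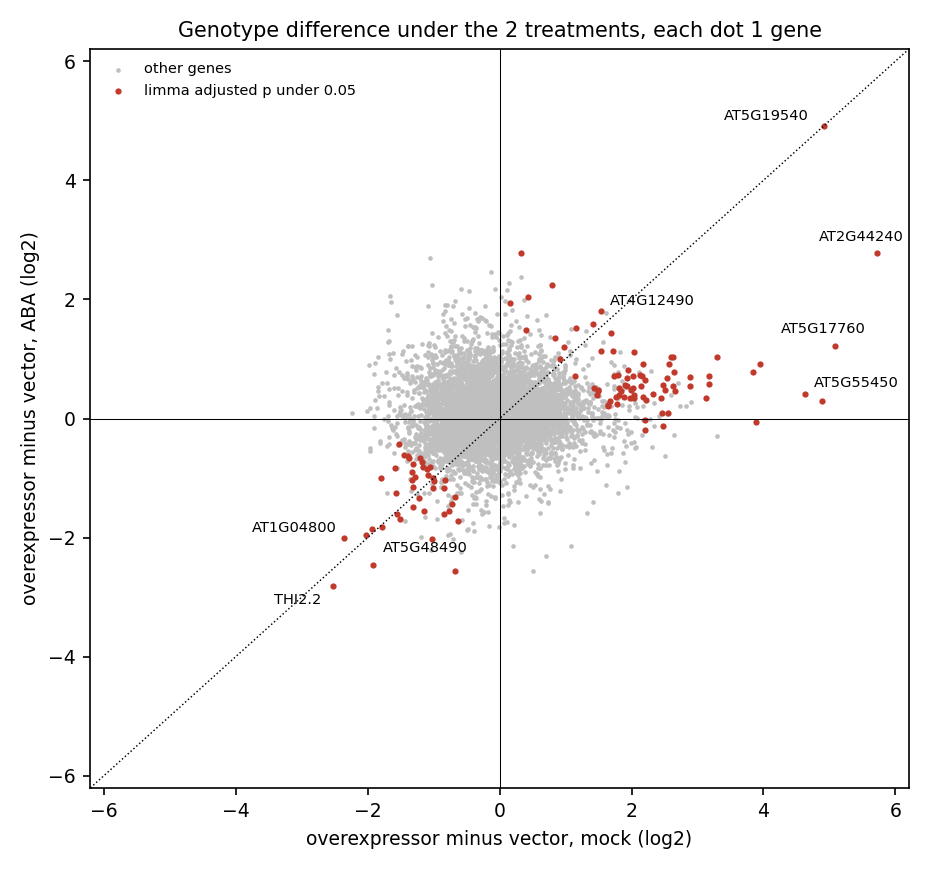
Overexpressor minus vector log2 difference of each of 7322 genes under mock (horizontal axis) and under ABA (vertical axis), with the 119 genes past the limma threshold in red and a dotted line of equal difference. AT5G19540 lies on the line at 4.92 and 4.91, which are lower limits, while most red genes on the right have a larger difference under mock, with medians of 2.04 under mock and 0.58 under ABA over the 78 higher genes.

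In total, 119 genes passed the limma threshold for genotype, 78 higher and 41 lower in the overexpressor, and 30 of them were at least 2-fold different in the same direction under both treatments. Much of this lay under mock: 70 of the 78 higher genes had their lowest signal on vector mock, and their median difference was 2.04 under mock and 0.58 under ABA, whereas the 41 lower genes had medians of -1.28 and -1.16. Genes chosen as higher in the overexpressor are mostly lowest on a vector array by selection. The count of 70 therefore largely restates the larger difference under mock, seen in 67 of the 78. With quantile normalization 5 genes passed, 2 higher and 3 lower, which were AT5G19540, AT2G44240, AT1G04800, AT4G29020 and AT5G48490. Without a trend in eBayes 1 passed, AT5G19540. With no filter 0 of 13356 passed by limma, and 562 had an unadjusted p under 0.05, no more than chance alone would give. Under mock, 359 genes were at least 2-fold higher and 397 lower in the overexpressor (410 and 261 with quantile normalization), and under ABA 288 were higher and 156 lower (165 and 220 with quantile normalization, 208 and 192 with arrays centred on the median). At least 2-fold in the same direction under both treatments were 23 higher genes, against 14.1 for independent lists, and 28 lower genes, against 8.46; with arrays centred on the median these were 18 and 35. Opposite directions were seen in 37 genes, of which 31 were lower under mock and higher under ABA, against 15.6 for independent lists. With quantile normalization this excess was smaller: 9 genes were lower under mock and higher under ABA, against 5.88, and 13 the reverse, against 12.3. The split of the arrays by genotype separated 27 genes by at least 2-fold, against 13 for the crossed split.

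The difference of the ABA effect between the genotypes, which has no replicate check, was, among the genes above the floor on every array, most negative for 4 genes with their lowest signal on the vector mock array and 1 with its lowest on overexpressor ABA. AT5G55450, a lipid transfer-like gene, was at a log2 signal of 4.62 on vector mock against 8.06 on vector ABA, 9.25 on overexpressor mock and 8.48 on overexpressor ABA. AT1G57630, which encodes a TIR-domain protein, was at 5.04 against 8.40, 8.92 and 8.34, and AT1G21520 at 5.01 against 7.89, 8.86 and 8.68. AT4G01870, a TolB-related gene, was at 5.08 on vector mock, 7.29 on vector ABA, 7.02 on overexpressor mock and 6.14 on overexpressor ABA. AT5G12110, an elongation factor 1-beta gene, was instead low on overexpressor ABA, at 4.02 against 6.59 to 7.18. The differences of these genes were -4.21, -3.94, -3.06, -3.09 and -3.07, in the order given. Among the same genes, the largest positive differences were those of AT1G23720, an extensin-like gene (3.75), AT3G03230 (3.28), AT3G49230 (2.99), AT1G32660 (2.97) and AT5G18550 (2.88), which were all left out by the filter at the 60th percentile. With the floor at the 40th percentile 4 of these 5 lay between 1.19 and 1.54, and all 5 had log2 signals of 6.72 or less on every array.

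Over all genes, 869 had an ABA effect at least 2-fold higher in the overexpressor and 495 at least 2-fold lower, and quantile normalization turned this split to 536 and 622. The excess of higher values lay among dim genes: in the lowest signal decile the median difference was 0.55, and in the highest it was -0.02. Of the sum of squared differences between the 4 arrays, 38.0% followed treatment, 33.2% genotype and 28.8% the interaction, which with 1 array per group also holds the spread between arrays.

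**Figure D4:**
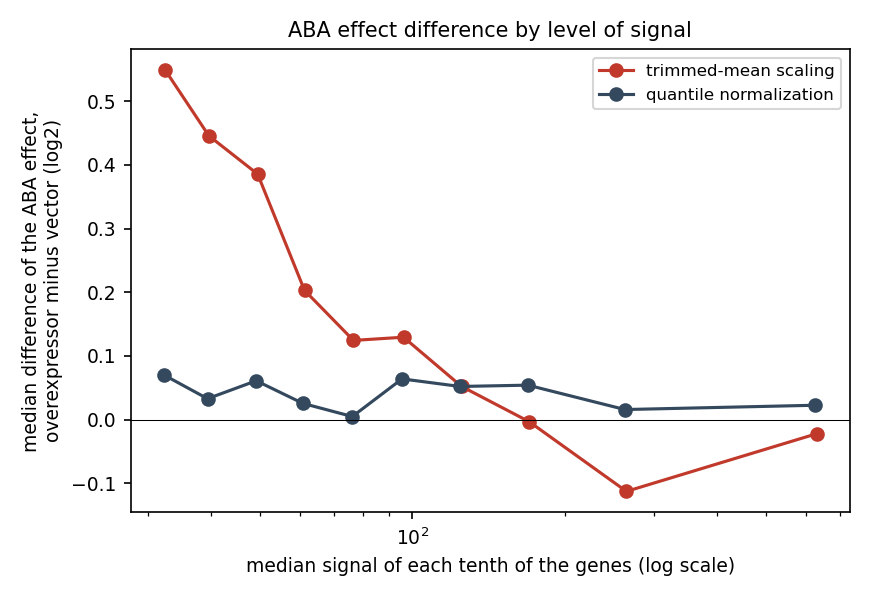
Median difference of the ABA effect, overexpressor minus vector (vertical axis, log2), in each of 10 equal classes of genes by signal (horizontal axis, log scale), with trimmed-mean scaling and with quantile normalization. With trimmed-mean scaling the median goes from 0.55 in the dimmest class to -0.02 in the brightest, and with quantile normalization it is 0.07 in the dimmest class.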

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

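All tests of explanations in this part were chosen after the results they bear on were seen. Of the genes named for the difference of the ABA effect, 9 were noted because ABA went with a higher signal in one genotype and a lower signal in the other; with 1 array per group, this difference was not tested. It was negative for AT5G55450 (-4.21), AT1G57630 (-3.94), AT4G01870 (-3.09) and AT1G21520 (-3.06), whose signals were higher with ABA in vector plants and lower with ABA in the overexpressor. It was positive for AT1G23720 (3.75), AT3G03230 (3.28), AT3G49230 (2.99), AT1G32660 (2.97) and AT5G18550 (2.88), whose lower signals lay near the floor: all of these but AT1G23720 lay between 1.19 and 1.54 with the floor at the 40th percentile.

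The negative differences belong to a set of 78 genes with an ABA effect at least 4-fold lower in the overexpressor, of which 65 had their lowest signal on the vector mock array and 55 their highest on overexpressor mock. A negative difference by itself places the lowest signal mostly on vector mock or overexpressor ABA. Likewise it places the highest mostly on vector ABA or overexpressor mock. Quantile normalization left the median difference of the 78 genes at -2.54, against -2.38 with trimmed-mean scaling. This could not decide on an array-wide intensity difference, since the genes were chosen for differences far beyond any such shift. With trimmed-mean scaling the median difference in the signal deciles ran only from -0.11 to 0.55. A shift of that size is too small to give -2.38. An exchange of the mock arrays between the genotypes would make the crossed split of the arrays the stronger one, but the split by genotype separated 27 genes by 2-fold against 13 for the crossed split (22 and 11 with quantile normalization, but 56 and 54 with no filter); it was the last of 3 tests tried, and the earlier ones, on the sign of the genotype difference outside the set under both treatments, decided nothing (the same sign for 11 of 14 genes beyond a log2 of 1.5, and for 48 against 31 at 2-fold). The state of the 1 pool of vector mock plants, such as a lower level of defence or handling responses in that pool, and an effect of ERD15 overexpression under mock cannot be told apart, since each group is 1 pool. Both may leave genes such as AT5G55450 lowest on the vector mock array, as were 65 of the 78.

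The positive differences go with dim genes, more than the negative ones do: 100 of the 112 genes with an ABA effect at least 4-fold higher in the overexpressor lay in the 3 lowest signal deciles, against 44 of the 78 genes of the negative set. A background difference between the arrays is a candidate explanation: the 9101 probe sets below the filter, which are outside the 7322 genes, showed a median difference of 0.77 with no floor, against 0.55 with or without the floor in the lowest decile of the genes used. This test took the place of one on quantile normalization, which equalizes dim signals by construction and brought the lowest decile to 0.07. Of the 112 genes, 41 kept a difference of at least 4-fold with quantile normalization. No biological explanation was tested for these genes.

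The 8730 probe sets with no gene name here are not among the 7322 genes compared; 5976 of them passed the same filter. Fitted with all probe sets, 178 of these were higher and 108 lower with ABA at a limma adjusted p under 0.05, and 105 were higher and 42 lower in the overexpressor; with quantile normalization 11 passed for genotype over all probe sets, named or not. Among those at least 2-fold changed in the same direction in both genotypes, the highest ABA effects were 4.22 and 3.36 on the log2 scale and the lowest -4.32 and -3.44. The probe set with 4.22 was at the floor on vector mock and that with -4.32 on both ABA arrays, so that these values are lower limits in size.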

How the results depend on the processing

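No paired analysis was possible because each group holds 1 array, so that the groups share only 1 replicate number. With 1 array per group no replicate can be left out of a group, and the additive model has no residual without 1 of the 4 arrays. The level of ERD15 was not run under any alternative. The use of all probe sets, the left-out arrays, the array splits and the share of genes with the larger effect in vector plants were added after seeing the data. The 20 genes named for ABA kept their direction and their side of the limma threshold with quantile normalization, and the 20 named for genotype kept their direction, while 15 lost the threshold; 4 of the named calls were lost with no floor and 1 with a floor at the 40th percentile. With the filter at the 60th percentile, 17 of the 20 named for ABA and 11 of the 20 named for genotype were still measured, and these kept their calls. The 10 genes named for the difference of the ABA effect kept its sign wherever they were measured, but 5 were left out by the filter at the 60th percentile. With the floor at the 40th percentile the differences of AT3G03230, AT3G49230, AT1G32660 and AT5G18550 lay between 1.19 and 1.54, under 4-fold, and that of AT5G12110 was -2.23, and with the 25th percentile added those of AT5G55450 and AT5G12110 were -3.64 and -2.35. All 119 genotype calls kept their direction with quantile normalization: their median size was 1.27 before and 1.28 after and their median SE 0.288 and 0.323, while the prior degrees of freedom fell from 2925 to 13.1 and 5 calls were left. In a test added after seeing the data, the quantile-normalized effects and SEs read at 2925 gave 126 calls, 99 of them among the 119, and those of trimmed-mean scaling read at 13.1 gave 20; effects and SEs were not exchanged one at a time. All 40 genes named for these effects lost the threshold with no filter, where 2282 genes had a residual of 0.

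The counts and medians that follow moved under an alternative, and the cause was not tested except as said. With quantile normalization, 115 genes passed for ABA and 5 for genotype, the correlation of ABA differences between the genotypes was 0.197, and the photosynthesis medians were -0.12 for genotype and 0.45 for the difference of the ABA effect. Without a trend in eBayes, 9 genes passed for ABA and 1 for genotype. With no filter, 0 of 13356 genes passed for either by limma, with 641 and 562 at an unadjusted p under 0.05. At 2-fold, 1322 genes differed for ABA in vector plants and 1212 for ABA in the overexpressor. For genotype, 1288 differed under mock and 1013 under ABA. The difference of the ABA effect counted 2509 genes and genotype under both treatments 89. The correlation was then 0.0831, the ABA list's median 0.90, and the genotype and crossed splits separated 56 and 54 genes.

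With a filter at the 60th percentile, which tests fewer genes, the counts in the same order were 350, 244, 337, 112, 489 and 22, with a correlation of 0.317, an auxin list median of 1.06 for ABA, splits of 13 and 0, and a median of 0.031 for the genes with symbols opening in CYP, which reversed. With the 25th percentile added in place of the floor they were 452, 313, 430, 185, 853 and 24, with a correlation of 0.188 and splits of 13 and 3. With the floor at the 40th percentile there were 390 genes for ABA in the overexpressor, 231 for genotype under ABA and 33 for genotype under both treatments, a correlation of 0.198 and a crossed split of 1.

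At 1.5-fold the counts were 1896, 1890, 2291, 1506 and 2981, with 437 for ABA in both genotypes and 315 for genotype under both treatments, and at 4-fold 105, 54, 75, 28 and 190, with 19 and 4. With all probe sets, named or not, which tests more of them, 523 passed for ABA and 262 for genotype, 350 and 112 were 2-fold changed in both comparisons, the correlation was 0.215 and the splits by treatment, by genotype and crossed separated 256, 64 and 31. With quantile normalization of these, 11 passed for genotype, 354 and 101 were 2-fold changed in both, the correlation was 0.256 and the splits separated 254, 58 and 25. Counts with an array left out hardly moved, since that array is in none of these comparisons and enters only through the pooled floor and filter. Without the overexpressor mock array, 736 genes differed for ABA in vector plants and 444 for genotype under ABA, against 745 and 444 with all arrays. Without the vector mock array, 614 differed for ABA in the overexpressor and 434 for genotype under ABA, against 627 and 444. Depth is signal over background here. With the lowest signals left unfiltered every limma call was lost, but 2282 genes then had a residual of 0. The prior degrees of freedom fell from 2925 to 0.889 in that setting. What caused the loss was not tested.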

Other observations

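In this part, the tests on bright genes, on mitochondrial genes and on families by symbol were chosen after the values were seen. Genes were grouped by the letters that open their symbol, where at least 5 were measured, with the plastid-encoded genes as a further group, which gave 28 groups. For ABA 5 groups lay outside the central 95% of random lists of like signal, for genotype 7 and for the difference of the ABA effect 3, against 1.4 by chance for each. The XTH genes, xyloglucan endotransglucosylase/hydrolases of the cell wall, stood out for both effects. Their 6 members had a median ABA effect of 0.74 (percentile 99.96) and a median genotype effect of -0.74 (percentile 0.01), which were 0.70 and -0.76 with quantile normalization. For ABA, XTH18 rose by 2.84 ± 0.27 while XTH33 fell by 2.14 ± 0.30. For genotype, XTH32 (-1.11 ± 0.28), XTH33 (-1.07 ± 0.30) and XTH16 (-0.93 ± 0.27) were lower in the overexpressor by limma, at adjusted p-values of 0.00901, 0.0293 and 0.0402, and none of these passed with quantile normalization.

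The tetraspanin genes (TET, 7 measured) had a median ABA effect of 0.55 (percentile 99.7) with no member past the threshold. Over both genotypes, the U-box genes (PUB, 8 measured) had 0.36 (percentile 98.8), with PUB19 and PUB43 (1.09 ± 0.30) past the threshold, and the beta-glucosidases (BGLU, 8 measured) also 0.36 (percentile 99.6), with BGLU40 (2.17 ± 0.27) past it. The genes with symbols opening in CYP (12 measured, cytochromes P450 except for the cyclophilin CYP71) had -0.24 (percentile 2.19), which was 0.03 with a filter at the 60th percentile. In the overexpressor, the aldehyde dehydrogenases (ALDH, 8 measured) had a median genotype effect of 0.39 (percentile 99.6), with ALDH7B4 (0.98 ± 0.27) past the threshold, though not with quantile normalization, and the autophagy genes (ATG, 8 measured) 0.27 (percentile 97.7). The beta-tubulin genes (TUB, 5 measured) had -0.48 (percentile 0.94), the TBL genes (12 measured) -0.33 (percentile 0.32) and the genes with symbols opening in GH (7 measured) -0.37 (percentile 1.66). The difference of the ABA effect was -0.66 for NRPB, subunits of RNA polymerase II (5 measured, percentile 1.44), and 0.79 for TRM (8 measured, percentile 98.3). Each of these medians, over both genotypes for ABA and over both treatments for genotype, kept its sign with quantile normalization, with the values as deposited and with arrays centred on the median.

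Plastid-encoded genes and bright photosynthesis genes were lower on the overexpressor mock array, where the 69 plastid genes had a median of -0.59 against vector mock (-0.28 with quantile normalization). As a group these 69 also lay outside the random lists for genotype over both treatments, with a median of -0.33 (percentile 0.035). The same held for the difference of the ABA effect, with 0.61 (percentile 100.0). With quantile normalization these medians were -0.12 and 0.41. For the 37 plastid genes with a signal of 1000 or more, brightness alone may account for the lower signal on that array, since their median of -0.57 lay at percentile 45.0 among nuclear lists of like signal, which had a median of -0.53. Their difference of the ABA effect did stand apart, with a median of 0.61 at percentile 99.93. Compression of bright signals stays open, since the bright spike-in (cre) was lowered less than bioC and bioD, by a log2 of 0.30 ± 0.10 SE, but not less than the dimmest, bioB (-0.11 ± 0.13), with 0.12 ± 0.12 over these 3, and signals brighter than cre were not covered. For the 32 dimmer plastid genes brightness is argued against, since their median was -0.70 against 0.01 for nuclear lists of like signal (percentile 0.0, and -0.68 with quantile normalization). This test was set before its result was seen. The 32 genes are among the 69, though, of which 66 were lower on that array, so their lower median is not an independent result. Less carry-over of RNA without poly(A) tails on that array stays open: the 25S control was lower by a log2 of -2.80, but the 7 mitochondrial genes measured had a median of -0.23, at percentile 24.5, too few to decide, and a change of plastid transcripts in the mock overexpressor plants was not tested.

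A hypothesis set before its test was that the 51 genes at least 2-fold different in the same direction between the genotypes under both treatments lie close together, as an inserted transgene or a linked segment of another background would give. Among these 51 genes there were 0 neighbouring pairs within 5 measured genes of each other, against a median of 2 in random sets of 51 genes, of which 16.3% also had none. This argues against a segment behind the set as a whole, not against one behind a single gene. Of the 10 measured genes nearest to AT5G19540, which was at least 30.2-fold higher in the overexpressor, the genotype effect ran from -1.40 for AT5G19570 to 0.39 for AT5G19440. AT5G19570 itself passed for genotype (limma adjusted p = 0.0254) and is not among the 51 because its difference was -1.80 under mock but -0.99 under ABA, just short of 2-fold.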
